A study of Mus musculus with 8 samples.

How the data were processed

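RNA was taken from Ly6C-high monocytes sorted from the bone marrow of male mice, in 4 COMMD10-deficient and 4 control samples, per the labels. Polyadenylated RNA was made into libraries and sequenced as single reads on a NextSeq, per the labels' protocols; no molecular identifiers are mentioned there, so PCR copies cannot be told from separate molecules, and the limits given for a count of 0 cover counting error only. The values used are raw counts of reads per gene as deposited by the authors, per the file headers. The submitters' processing notes name the genome build GRCm38 and the tools cutadapt, STAR 2.7.3a, HTSeq 0.12.4 and DESeq2, without saying what each did; strandedness is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. The table lists 15566 genes and a row for Cre, and holds only genes whose highest count is at least 6. A block of normalized values in the same table was not used here. The Cre row was left out of the library sizes and tests and is reported by itself, in CPM of the total that includes it. Every one of the 8 columns of counts was matched to a sample by its title.

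Total counts were 14231121 to 31040255 in the controls and 17100023 to 30723249 in the deficient libraries. Libraries of a group were compared by a chi-square test of their counts over genes with a summed count of at least 20; the statistic was 2.88 to 23.4 per degree of freedom, so no library was a copy of another, and each counted as 1 replicate. The labels carry no batch, day or litter, and replicate numbers follow the order of deposit, so nothing was paired. The sample titles carry running numbers that are lower in every control than in every deficient sample. What these numbers stand for is not given, and an order of handling behind them could not be told apart from genotype.

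The design, the lists and the rule for naming genes were fixed before the data were examined. Counts were filtered with filterByExpr (minimum count 10, minimum total 15), which left 12938 genes, scaled with TMM factors and fitted with edgeR 4.0.16 (R 4.3.3) by robust quasi-likelihood, with genotype as the only term. Tests were two-sided, and an adjusted p (Benjamini-Hochberg) under 0.05 counted as past the threshold, with no limit on the fold. Standard errors of log2 fold changes were derived from the F statistic. CPM values of tested genes are TMM-scaled, and ± gives the SD over 4 libraries; those of Cre, Ly6g and Kit and of a single count are not TMM-scaled. The targeted genes and the list scores were also tested by exact permutation over the 70 assignments of 4 against 4, whose smallest two-sided p is 0.0286. Genes were placed with GENCODE M21, an annotation of GRCm38; 12926 of the tested identifiers matched.

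The 21 gene lists and 11 marker lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 between genes, two-sided, with adjustment over all 32. They cover trafficking complexes of COMMD proteins, primary granules, secondary and tertiary granules, neutrophil-like, dendritic-like, Ly6C-low and classical monocytes, myeloid transcription factors, interferon, NF-kB, inflammasome, lysosome, phagocyte receptor, chemotaxis, cell cycle, cholesterol, glycolysis, oxidative phosphorylation, ribosomal protein, immediate early and unfolded protein response genes. The marker lists cover mature neutrophils, neutrophil precursors, stem and progenitor cells, erythroid cells, megakaryocytes, B cells, T and NK cells, eosinophils with basophils and mast cells, dendritic cells, macrophages and stroma. The lists share genes, up to 12 between a pair, and many granule markers are also expressed by monocytes. Symbols of 4 members were matched through RefSeq synonyms (Siglecf is Siglec5 in the table). Each list was also tested with an estimated correlation and with fry.

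Genes are named by this rule: Commd10, Lyz2 and Lyz1; among genes past the threshold with a mean of at least 5 CPM, no overlap between groups and an assigned name, the 12 with the largest increase and the 12 with the largest decrease; of each list, up to 4 members past the threshold with the smallest p, or where fewer than 2 passed, the 2 with the smallest p; and the 3 most abundant members of the marker lists discussed as sources of signal. 1 gene picked by this rule is not reported here. Ly6g and Kit are named as well because the gate excludes the cells that carry them. Other genes in the closing part were chosen after their values were seen.

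The pipeline was tested on simulated data: in 5 simulated tables of 12938 genes each, with 200 genes changed per table between deficient and control, it recovered 42.1% of genes changed 1.25-fold, 72.2% of those changed 1.5-fold and 87.0% of those changed 2-fold, and 8.59% of its calls were false. With the cell cycle list shifted by 0.3 on the log2 scale and the others left alone, that list was called, with 2 of 32 lists called in all. Genes were simulated independently of each other, whereas the estimated correlation within the real cell cycle list was 0.84. The simulated shift was also larger than the median of 0.15 measured for that list. The simulation is therefore no check of the list test on correlated genes. Alternatives tried were other scaling factors, other filters, DESeq2 1.42.0, limma-voom with and without sample weights, a surrogate variable from sva 3.50.0, other thresholds, and leaving out each library in turn. A planned overlap with fold changes of the authors was not run, since no such values were used here.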

Results

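Messenger RNA was sequenced from Ly6C-high monocytes sorted from the bone marrow of male mice, 8 weeks old and untreated. These cells are the classical monocytes that leave the marrow for the blood and inflamed tissue. In 4 libraries the cells came from mice in which Commd10, a member of the COMMD family of protein trafficking adaptors, was deleted by LysM-Cre, a recombinase expressed in myeloid cells. The 4 control libraries came from littermates that carried the floxed gene. The gate took live CD45+ CD11b+ CD115+ cells and left out Ly6G+ neutrophils and CD117+ progenitors. Total counts were 25241865, 22364278, 14231121 and 31040255 in control 1 to 4, and 30723249, 30171838, 17100023 and 29886979 in deficient 1 to 4. A single count stood for 0.0322 to 0.0703 CPM (counts per 1000000 counts of the library). Between libraries of a group, log2 CPM values correlated at r = 0.991 to 0.995 across genes, and every pair differed by more than counting noise. The labels do not say which libraries came from which mouse or litter, so p-values measure the spread between these samples.

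The first comparison asked whether the libraries carry the genotype of their labels. Commd10 (ENSMUSG00000042705, GRCm38 chromosome 18, 46958816 to 47234284, plus strand) was lower in all 4 deficient libraries, at 21.3 ± 2.17 CPM (SD, n = 4) against 29.2 ± 1.46 CPM (SD, n = 4) in the controls. Its level was 73.0% of the control level, a log2 fold change of -0.46 (SE 0.07, adjusted p = 0.0292 with edgeR; exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 can give). Cre itself was counted in the table: it had 987, 499, 569 and 740 counts in deficient 1 to 4, or 26.7 ± 7.74 CPM (SD, n = 4). It had 0 counts in every control library, where a count of 0 allows up to 0.211 CPM in the shallowest one. The counts cover the whole gene and the deleted exons are not given in the sources used here, so the Commd10 level is no measure of how many cells lost the gene. The adjusted p of Commd10 was above 0.05 without control 1 (0.0646), control 3 (0.0994), control 4 (0.113) or deficient 4 (0.138), with log2 fold changes between -0.53 and -0.42 over the fits that left out 1 library.

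Lyz2, the lysozyme gene into which LysM-Cre is inserted, fell in the deficient libraries. Lyz2 (ENSMUSG00000069516, GRCm38 chromosome 10, 117277331 to 117282321, minus strand) was at 10380 ± 656 CPM (SD, n = 4) against 21036 ± 1226 CPM (SD, n = 4), or 49.3% of the control level (log2 fold change -1.02, SE 0.05, adjusted p = 2.51e-06). Lyz1 (ENSMUSG00000069515, chromosome 10, 117287797 to 117292868, minus strand), its neighbouring paralog, rose to 84.2 ± 21.3 CPM from 27.8 ± 5.18 CPM (SD, n = 4 each; log2 fold change 1.60, SE 0.22, adjusted p = 0.0428). Both genes had an exact permutation p of 0.0286, and their reads are partly alike in sequence, which makes the lower Lyz1 values the less certain. Lyz2 stayed past the threshold whichever library was left out. Lyz1 did not without control 1 (adjusted p = 0.0838), control 3 (0.124), control 4 (0.153), deficient 2 (0.0582) or deficient 4 (0.138).

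**Figure D1:**
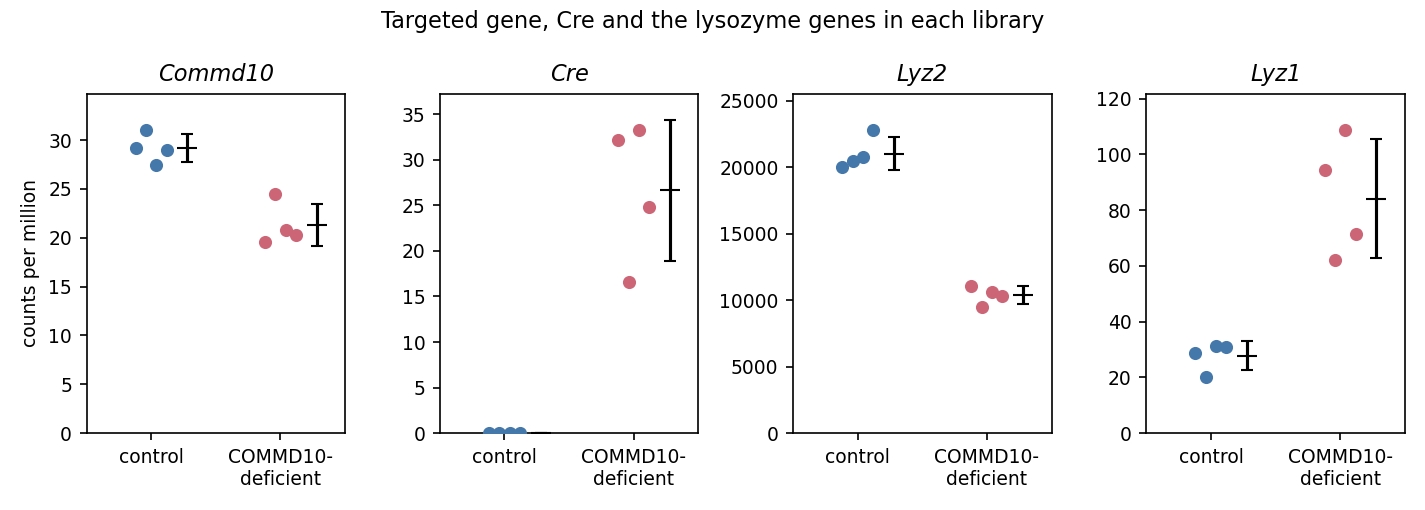
CPM of Commd10, Cre, Lyz2 and Lyz1 in the 4 control (blue) and 4 COMMD10-deficient (red) libraries, each point a library, with the group mean and SD (n = 4) as black bars. Commd10 and Lyz2 are lower in every deficient library than in every control, Lyz1 is higher in every deficient library, and Cre has 0 counts in the controls.

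The main comparison asked how the monocyte transcriptome differs between genotypes. Of 12938 genes tested, 113 changed, of which 46 rose and 67 fell in the deficient monocytes. Most of the changes were small: 88 of the 113 were under 1.5-fold, the median absolute log2 fold change was 0.35, and 7 genes reached 2-fold. Among the genes that rose most were Hsph1 (log2 fold change 0.73, SE 0.13, adjusted p = 0.0459), Dnaja1 (0.56, SE 0.07, adjusted p = 0.00960) and Hspa8 (0.37, SE 0.06, adjusted p = 0.0292), each of which encodes a cytosolic chaperone or cochaperone. Cirbp, a cold-inducible RNA-binding protein, fell to 23.5 ± 2.05 CPM from 35.9 ± 1.87 CPM (SD, n = 4 each; log2 fold change -0.61, SE 0.07, adjusted p = 0.00783).

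In all 113 genes the 4 deficient values lay entirely above or below the 4 control values, as they did in 1634 tested genes (12.6%, where chance gives 2.86%). An unadjusted p under 0.05 was reached by 3100 genes, where 647 would be expected by chance. Both chance values are averages, around which counts spread widely when genes vary together, and neither count was made for other splits of the libraries. The number past the threshold depended on single libraries. Without control 1, 3 or 4 it was 1, 3 and 8, and without deficient 2 or 4 it was 29 and 2; it was 298 without control 2, 522 without deficient 1 and 479 without deficient 3. Without the shallowest library of each group, a choice made after the data were seen, it was 1. With DESeq2 it was 841, and with a surrogate variable in the design 14.

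Besides Lyz1, Hsph1, Dnaja1 and Hspa8, the genes that rose most included Ppef2, a protein phosphatase (log2 fold change 0.76, SE 0.11), and Idi1, an enzyme of isoprenoid and cholesterol synthesis (0.60, SE 0.10). Usp31, a ubiquitin protease (0.53, SE 0.07), Pprc1, a transcriptional coactivator of mitochondrial genes (0.51, SE 0.08), and Ccnd3, the cell cycle regulator cyclin D3 (0.38, SE 0.06), followed. Nt5dc3 (0.37, SE 0.08), the galactosyltransferase gene B4galt5 (0.36, SE 0.05) and the transporter gene Slc37a3 (0.36, SE 0.07) also rose. The adjusted p-values of these 8 genes lay between 0.00997 (Usp31, B4galt5) and 0.0473 (Nt5dc3).

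Among the genes that fell most after Lyz2 were Abca6, a lipid transporter of the ABC family (log2 fold change -0.97, SE 0.17), and Coq8a, which serves coenzyme Q synthesis (-0.92, SE 0.15). Vangl2, a planar cell polarity gene (-0.84, SE 0.15), and the ion channel genes Kcnq3 (-0.79, SE 0.14) and Trpv4 (-0.61, SE 0.12) fell too. The remaining ones were Rusc2 (-0.63, SE 0.08), Chst1, a sulfotransferase gene (-0.60, SE 0.13), Pdk2, an inhibitory kinase of pyruvate dehydrogenase (-0.59, SE 0.12), Ick (-0.56, SE 0.12) and Nudt16 (-0.56, SE 0.07). Their adjusted p-values lay between 0.00997 (Rusc2, Nudt16) and 0.0499 (Chst1). All 40 genes named here or below that passed the threshold, those of the closing part included, kept their sign whichever library was left out. None of them had values that overlapped between groups, so leaving out 1 library could hardly change a sign. The kept signs are therefore no separate evidence of stability. Lyz2 alone of the 40 kept its call in every fit that left out 1 library, and Cirbp lost its call only without control 1 (adjusted p = 0.0563).

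**Figure D2:**
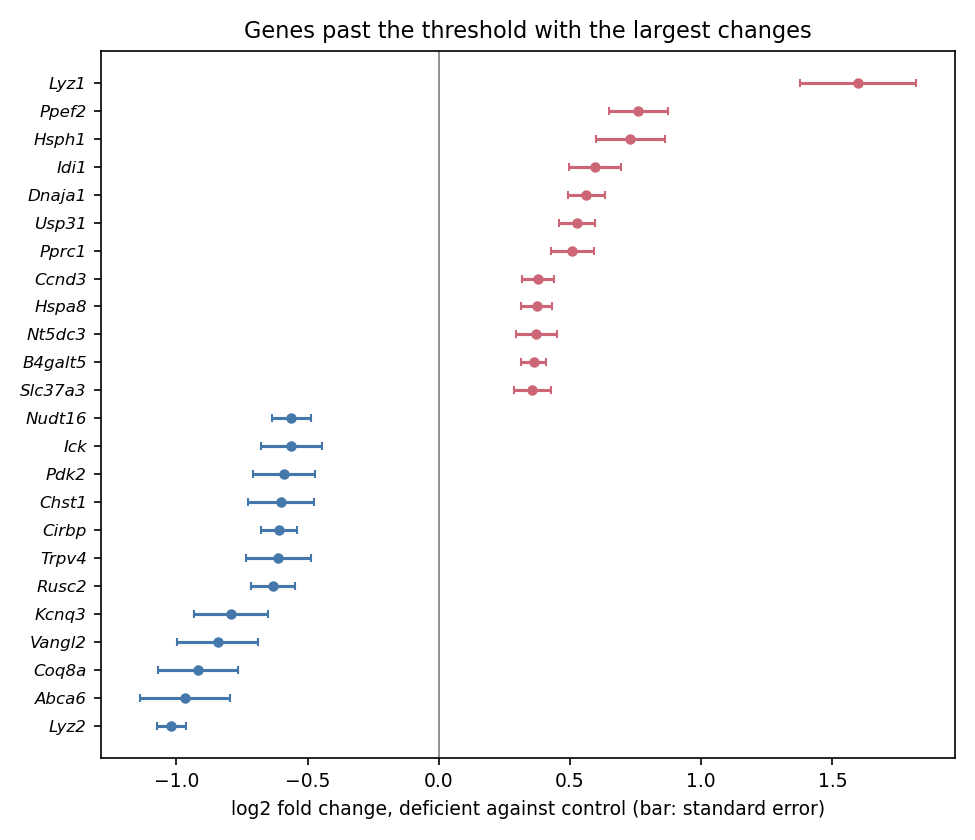
Log2 fold change (deficient against control, 4 libraries each) of the 12 genes with the largest increase (red) and the 12 with the largest decrease (blue) among those past the threshold with at least 5 CPM and no overlap between groups; bars are standard errors. The values run from -1.02 for Lyz2 to 1.60 for Lyz1, and most lie within 1 log2 unit of 0.

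The title of the series concerns a neutrophil-like fate of these monocytes, so lists of granule, neutrophil-like and dendritic-like monocyte genes were tested with 28 others. Genes of primary granules, the enzyme stores of neutrophils and their precursors, were higher in the deficient libraries as a list: all 8 measured members were higher, with a median log2 fold change of 0.65 (camera adjusted p = 8.47e-05; adjusted p = 0.617 with an estimated correlation). None of the 8 passed the threshold over all genes and 7 did when adjusted over the list alone. Elane, neutrophil elastase, was at 98.2 ± 17.3 against 58.5 ± 9.62 CPM (SD, n = 4 each; log2 fold change 0.75, SE 0.16, adjusted p = 0.0654), and Mpo, myeloperoxidase, had a log2 fold change of 0.82 (SE 0.18, adjusted p = 0.0736). The neutrophil-like monocyte list was higher too, with a median of 0.40 over 21 genes, of which 17 were higher (adjusted p = 0.00480; adjusted p = 0.617 with an estimated correlation); 0 passed over all genes and 3 adjusted over the list alone. The markers of neutrophil precursors, which share 12 genes with that list, had a median of 0.51 with 13 of 13 higher (adjusted p = 4.09e-04; adjusted p = 0.617 with an estimated correlation), 0 past the threshold over all genes and 3 adjusted over the list alone. Their most abundant gene, Chil3, had a log2 fold change of 0.51 (SE 0.18, adjusted p = 0.158), and Prtn3 one of 0.93 (SE 0.35, adjusted p = 0.173). The primary granule list shares 4 genes with the neutrophil-like list and 5 with the precursor markers, so these lists are not separate results.

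Genes of secondary and tertiary granules, which are made later, did not pass as a list (median 0.25, 11 of 14 higher, adjusted p = 0.0647), with 0 genes past the threshold over all genes and 3 adjusted over the list alone. The members nearest to it were Mmp25 (log2 fold change 0.66, adjusted p = 0.0600) and Slpi (0.30, adjusted p = 0.0736). Markers of mature neutrophils did not pass either (median 0.32, 9 of 15 higher, adjusted p = 0.505; 0 genes past the threshold over all genes or over the list alone). Among them, Il1r2 and Trem3 had log2 fold changes of 0.73 and 0.48, and the most abundant, Csf3r, Cd177 and S100a8, had -0.06, -0.43 and 0.58. Ly6g, the antigen that the gate excludes, was at 0 to 0.322 CPM in the controls and 0.232 to 0.423 CPM in the deficient libraries. These values stand for 0 to 10 and 7 to 13 counts, too few to pass the filter, so the difference was not tested.

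The dendritic-like monocyte list was lower. It holds antigen presentation genes together with other genes, such as Irf4, Flt3 and Tmem176b. Of its genes, 18 of 19 were lower, with a median log2 fold change of -0.52 (camera adjusted p = 2.89e-04, or 0.617 with an estimated correlation). Past the threshold were 0 over all genes and 4 adjusted over the list alone. Tmem176b (-0.34, SE 0.07, adjusted p = 0.0539) and the transcription factor gene Irf4 (-0.78, SE 0.20, adjusted p = 0.0889) came nearest. With 1 library left out, the median of the dendritic-like list ranged from -0.70 to -0.35. Its score (mean log2 CPM relative to all 8 libraries) was lower in control 2 (-0.18) than in deficient 1 (0.04) and deficient 3 (0.13). Genes of Ly6C-low monocytes, the patrolling subset, were also lower as a list (median -0.27, 15 of 19 lower, adjusted p = 0.0360; adjusted p = 0.617 with an estimated correlation), with 0 genes past the threshold over all genes or over the list alone. Fabp4 and Cd36 were the closest, at -1.13 and -0.91 (edgeR adjusted p = 0.0862 and 0.114). Both were low, Fabp4 at 0.328 against 0.767 CPM and Cd36 at 2.35 against 4.34 CPM in deficient and control libraries. That list's call was lost without control 2, 3 or 4 or deficient 2, with adjusted p-values up to 0.211.

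Several lists of markers of other cells were lower. Erythroid markers were lower as a list (median -0.67, 9 of 10 lower, camera adjusted p = 0.00480, or 0.617 with an estimated correlation). Hbb-bs was at 171 ± 53.7 against 284 ± 67.3 CPM (SD, n = 4 each). Hba-a1 and Hba-a2, whose reads are nearly identical, had log2 fold changes of -0.76 and -0.73. Ermap had -0.86, at only 0.630 against 1.05 CPM. B cell markers (median -0.41, 11 of 11 lower, adjusted p = 0.0223; adjusted p = 0.617 with an estimated correlation), eosinophil, basophil and mast cell markers (median -0.78, 7 of 8 lower, adjusted p = 0.0340; adjusted p = 0.617 with an estimated correlation) and markers of conventional and plasmacytoid dendritic cells (median -0.41, 9 of 11 lower, adjusted p = 0.0251; adjusted p = 0.617 with an estimated correlation; 4 genes shared with the dendritic-like list) were lower as well. All 4 lists had 0 genes past the threshold over all genes; adjusted over the list alone, 2 B cell and 4 dendritic cell markers passed. In the B cell list, Ebf1, Ighm, Cd79b and Igkc had log2 fold changes of -0.81, -0.28, -0.41 and -0.38. Ear6, Prss34, Prg2, Epx and Siglec5 had -1.23, -0.76, -0.80, -1.16 and -0.46, all at group means of 7.59 CPM or less, and Clec9a, Clec10a, Tcf4 and Bst2 had -0.98, -0.23, -0.06 and 0.06. With 1 library left out, Prg2 ranged from -1.06 to -0.47 and Epx from -1.48 to -0.45. Epx was at 9.34 CPM in control 2, against 1.56 to 4.01 CPM in the other controls. The B cell call was lost without control 4, deficient 1 or deficient 2 (adjusted p up to 0.152), the dendritic cell call without control 4, deficient 2 or deficient 4 (up to 0.0803), and the eosinophil call without control 1, 2 or 3 or deficient 1 or 3 (up to 0.0959). Over these fits the medians ranged from -0.61 to -0.15 (B cell), -0.60 to -0.19 (dendritic cell) and -0.91 to -0.45 (eosinophil).

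Libraries also differed within each genotype. The first principal component, with 37.2% of the variance of the 1000 most variable genes, ran from control 3 (-16.9) and control 4 (-12.7) to deficient 4 (13.3) and deficient 2 (18.7), with the other 4 libraries between -2.89 and 2.46 (exact permutation p = 0.0571 between genotypes, two-sided). The neutrophil-like score, the mean log2 CPM of the list relative to all 8 libraries, was 0.38 in deficient 2 and 0.40 in deficient 4 but -0.18 in deficient 3, below the 0.05 of control 1. The score difference between genotypes was 0.36 for the neutrophil-like list (exact permutation p = 0.0857, two-sided; 0.274 adjusted over 32 lists), 0.59 for primary granules (0.0571; 0.274) and -0.46 for the dendritic-like list (0.143; 0.327).

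**Figure D3:**
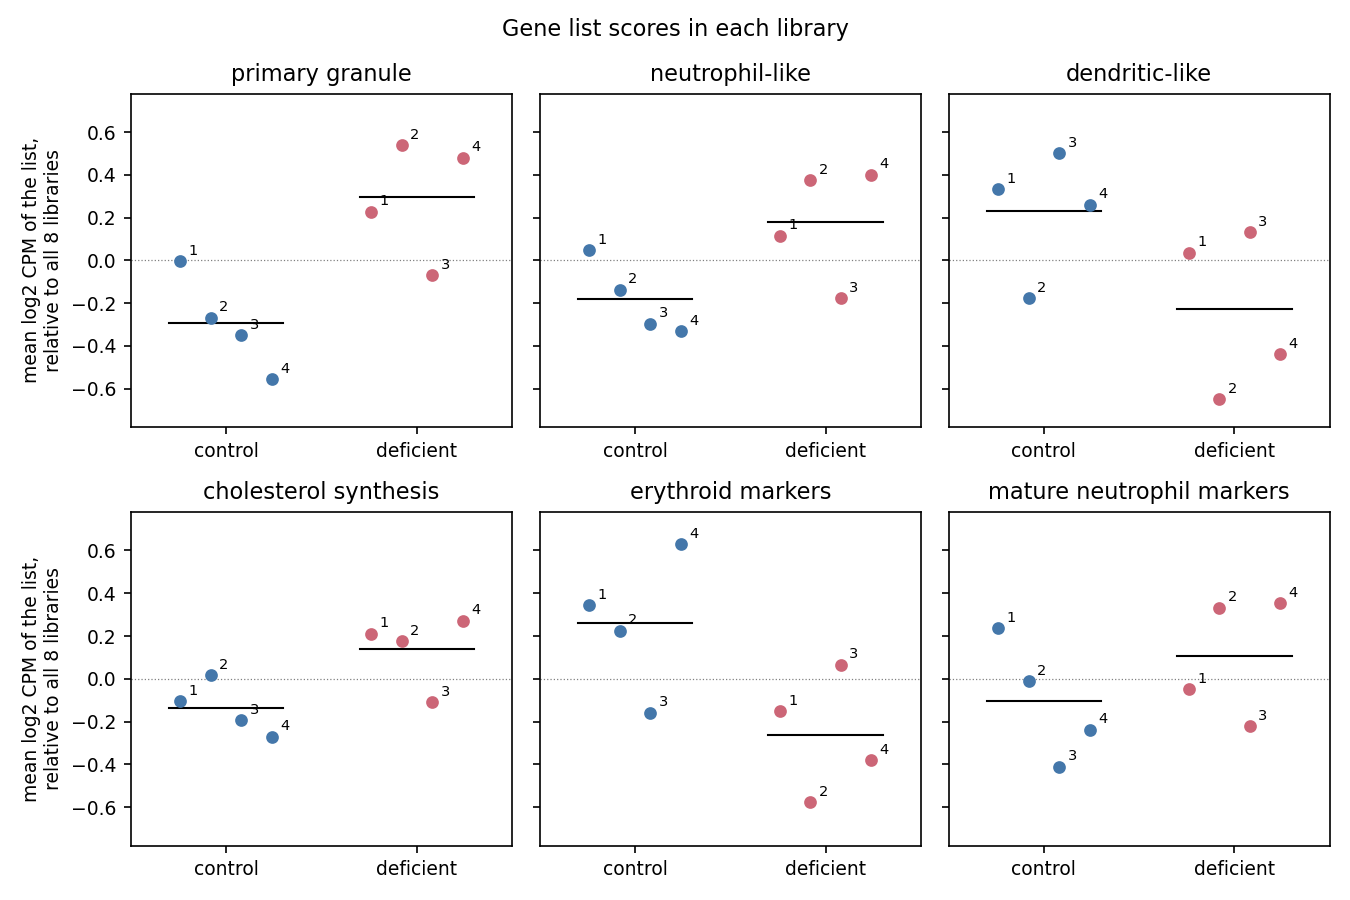
Score of 6 gene lists (mean log2 CPM of the list's genes relative to the mean of all 8 libraries) in each control (blue) and deficient (red) library; digits are replicate numbers and black lines are group means. Deficient 3 lies at -0.07 for primary granules and -0.18 for the neutrophil-like list, within the range of the controls, while deficient 2 and 4 lie at 0.54 and 0.48 and at 0.38 and 0.40.

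Genes of cholesterol synthesis and uptake were higher in the deficient monocytes. Idi1 and Dhcr7 (log2 fold change 0.33, SE 0.07, adjusted p = 0.0459) rose, 21 of the 22 measured genes were higher and the median was 0.28 (adjusted p = 7.80e-07; adjusted p = 0.617 with an estimated correlation). Adjusted over the list alone, 13 genes passed. Deficient 3 (score -0.11) again lay among the controls (-0.27 to 0.02).

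The lists of cell cycle, oxidative phosphorylation and unfolded protein response genes were higher too. All 40 cell cycle genes were higher, with a median of 0.15 (adjusted p = 1.85e-06; adjusted p = 0.617 with an estimated correlation), led by E2f1 (0.20, adjusted p = 0.0908) and Ccne2 (0.43, adjusted p = 0.0973). With 1 library left out, the cell cycle median ranged from 0.07 to 0.19. In oxidative phosphorylation, 72 of 78 genes were higher with a median of 0.10 (adjusted p = 6.84e-07; adjusted p = 0.617 with an estimated correlation), Atp5k and Ndufa4 having 0.31 and 0.23. This median ranged from 0.06 to 0.13 with 1 library left out. Deficient 2 had the highest score (0.19), while deficient 1 and 3 (-0.012 and -0.016) lay just above control 2 (-0.018). The unfolded protein response list had 17 of 21 genes higher (median 0.22, adjusted p = 3.88e-04; adjusted p = 0.617 with an estimated correlation), with Xbp1 at 0.22 (adjusted p = 0.0736) and Edem1 at 0.16 (adjusted p = 0.0754). Its median ranged from 0.13 to 0.26 with 1 library left out. Deficient 1 and 3 (scores -0.04 and -0.10) lay among the controls (-0.14 to 0.05), below deficient 2 and 4 (0.30 and 0.16). Each of these 3 lists had 0 genes past the threshold over all genes; adjusted over the list alone, 3 genes of the unfolded protein response passed and 0 of the others. The highest cell cycle score was that of deficient 2 (0.29), against 0.06 in control 1 and -0.04 in deficient 1. Glycolysis and hypoxia genes did not pass as a list (median 0.16, adjusted p = 0.0686), although the phosphofructokinase gene Pfkp rose (0.25, SE 0.04, adjusted p = 0.0292) and the glucose transporter gene Slc2a1 had 0.37 (adjusted p = 0.0552); adjusted over the list alone, 6 genes were higher and 2 lower.

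Immediate early genes, which respond within minutes to cell handling and signalling, were lower as a list (median -0.32, 19 of 23 lower, adjusted p = 0.00779; adjusted p = 0.617 with an estimated correlation), with 0 genes past the threshold over all genes or over the list alone. Ier5 and Ier2 had log2 fold changes of -0.36 and -0.24. The scores spread within both groups, from -0.43 in control 1 to 0.53 in control 2, and deficient 1 (0.24) stood apart from the other deficient libraries (-0.26 to -0.20). Without control 2 the call was lost (adjusted p = 0.0922).

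The lists of inflammation and of monocyte identity did not shift as a whole. Interferon-stimulated genes had a median of -0.05 (14 of 34 higher, adjusted p = 0.789), with Ifi27l2a and Oas1a at 0.20 and 0.22, and 0 past the threshold when adjusted over the list alone. NF-kB response genes had -0.07 (adjusted p = 0.319), with Sod2 at 0.16 and Relb at -0.20, which were the 1 higher and 1 lower gene adjusted over the list alone. In the inflammasome list (-0.08, adjusted p = 0.305), Mefv and Pycard had 0.19 and 0.27 and were the 2 genes that passed adjusted over the list alone. Classical monocyte genes had a median of -0.01 (adjusted p = 0.866); Lyz2 was the 1 gene of this list past the threshold over all genes, Fcgr1 had 0.40 (adjusted p = 0.0736), and adjusted over the list alone 3 genes were higher and 2 lower. Myeloid transcription factors had a median of 0.00 (adjusted p = 0.866), with Zeb2 at -0.28 and Ets2 at 0.54 (adjusted p = 0.0585 for both), and 2 higher and 4 lower adjusted over the list alone.

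Among trafficking and surface genes, the COMMD, CCC, retriever and WASH complexes had a median of 0.01 over 20 genes (adjusted p = 0.842). Commd10 was the 1 gene of this list that changed, over all genes and adjusted over the list alone, and Commd1 had 0.23 (adjusted p = 0.112). In this list and in those of classical monocyte genes and myeloid transcription factors, the mean (-0.01, 0.02 and -0.09) differed in sign from the median or from the direction of the test. Lysosome genes had a median of 0.02 (adjusted p = 0.192), with Ctsz at 0.24 and Tfec at 0.29, the 2 that passed adjusted over the list alone. Phagocyte oxidase and receptor genes had a median of 0.00 (adjusted p = 0.799), with the mannose receptor gene Mrc1 at 8.34 ± 2.32 against 16.4 ± 3.39 CPM (SD, n = 4 each, adjusted p = 0.0646), and 1 higher and 4 lower adjusted over the list alone. Chemotaxis and adhesion receptors had 0.04 (adjusted p = 0.344), with C3ar1 at -0.92 (adjusted p = 0.0631), Cxcr4 at 0.45 (adjusted p = 0.0718), and 6 higher and 2 lower adjusted over the list alone. Cytosolic ribosomal protein genes had -0.01 (25 of 75 higher, adjusted p = 0.262), with Rps27l at 0.23 and 0 past the threshold adjusted over the list alone.

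The remaining marker lists did not pass. Macrophage markers had a median of -0.12 over 13 genes (adjusted p = 0.802), in which the heme oxygenase gene Hmox1 rose (0.34, SE 0.07, adjusted p = 0.0465) while Adgre1 and Axl had -0.12 and -0.30; adjusted over the list alone, 1 was higher and 1 lower. Stem and progenitor markers had -0.18 over 8 genes (adjusted p = 0.124), with Sox4, Flt3, Cd34 and Myb at -0.63, -0.66, -0.23 and 0.09, and Kit, which encodes the excluded CD117, at 0.134 to 0.391 CPM. Megakaryocyte markers (-0.14 over 4 genes, adjusted p = 0.344), T and NK cell markers (0.13 over 2 genes, adjusted p = 0.967) and stromal markers (0.17 over 3 genes, adjusted p = 0.866) had few measured members. Of these, Vwf, Gp1ba, Nkg7, Cd2 and Sparc were at 1.04 CPM or less in both groups, and Pecam1 had a log2 fold change of -0.14. In the last 4 lists 0 genes passed, over all genes or over the list alone.

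Over all 32 lists, 14 passed the threshold with camera's preset correlation, 7 higher and 7 lower. With an estimated correlation 0 passed and 0 had an unadjusted p under 0.05. The rotation test fry asks whether a list moves on balance in a direction. It passed 0 (8 at an unadjusted p under 0.05, smallest adjusted p = 0.176), while 10 passed its test for changes in either direction. Of these 10, only the primary granule, neutrophil precursor, Ly6C-low and cholesterol lists had also passed with camera. The smallest adjusted p-values of that fry test were 1.83e-04 and 0.00103. They belonged to the classical monocyte list, which holds Lyz2, and the COMMD list, which holds Commd10. Of the 35 ways to split the 8 libraries into groups of 4, 8 gave at least 14 lists, and the highest of the others gave 20.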

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

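No test in this part was chosen after the results were seen: a library was taken up where its gap to the nearest other library of its group exceeded a fixed share of the group's range. Of 265 groups of 4 values examined, 15 exceeded it, where chance gives about 1 in 20, or 13. The number is therefore close to what chance gives, and no explanation was weighed for single values.

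Most of these values belonged to control 2 (5) and deficient 3 (4). In control 2, Fcgr1 was at 185 CPM (other controls 140 to 147), C3ar1 at 2.21 CPM (3.92 to 4.22) and Cxcr4 at 296 CPM (260.3 to 262), the stem and progenitor score was -0.080 (0.19 to 0.21), and the dendritic cell marker score was -0.12 (0.32 to 0.33). In deficient 3, the total was 17.1 M counts (29.9 M to 30.7 M), Pdk2 was at 9.59 CPM (6.35 to 6.89), Sox4 at 2.05 CPM (1.20 to 1.33) and Ighm at 426 CPM (381 to 387).

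In deficient 1, Hsph1 was at 35.2 CPM, against 52.6 to 53.6 in the other deficient libraries, and the immediate early score was 0.24 (-0.26 to -0.20). Ier5 was at 179 CPM in control 1 (234 to 238 in the other controls) and Edem1 at 309 CPM in the same library (314.6 to 314.7). Atp5k was at 37.4 CPM in control 4 (33.6 to 34.2), and Gp1ba at 0.502 CPM in deficient 4 (0.632 to 0.650).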

How the results depend on the processing

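The thinned counts, the surrogate variable for lists, the fit without the shallowest library of each group and the removal of GC and length trends were chosen after the data were seen. The number of changed genes (113; 46 higher, 67 lower) stayed within 1.5 times under other scaling factors, both other filters and limma-voom. It was 841 (402 and 439) with DESeq2, 772 (332 and 440) with sample weights, 14 (6 and 8) with a surrogate variable, 217 (121 higher) with GC and length trends removed, and 73 (40 lower) with all libraries thinned to the shallowest. It was 1 (0 and 1) without the shallowest library of each group, where fewer samples remain, and 7 at 2-fold, 8 at an adjusted p under 0.01 and 921 under 0.1. Leaving out 1 library gave 1 to 522 genes (0 to 225 higher, 1 to 311 lower). Of the 40 named genes past the threshold, those of the closing part included, 40 remained so without deficient 1 or 3, 37 without control 2, 19 without deficient 2, 8 without control 4, 3 without control 3, 2 without deficient 4 and 1 without control 1. Commd10 ranged from -0.53 to -0.42 when 1 library was left out and was -0.47 without the shallowest library of each group (adjusted p = 0.0904; 6.64e-05 to 0.138 over all settings). The 14 lists fell to 0 with an estimated correlation and 0 with fry; leaving out 1 library gave 12 to 15, of which 11 to 13 were among the 14. The surrogate variable gave 12 (10 of the 14), thinned counts 11 (11), and the fit without the shallowest libraries 15 (13). Among genes that never passed, signs changed for Gp1ba (0.033, thinned), Nkg7 (-0.018, surrogate variable; -0.29, thinned), Cd34 (0.010, surrogate variable), Cd2 (0.019, sample weights), Sparc (-0.023, without the shallowest libraries), and with 1 library left out for Cd2 (-0.35 to 0.050), Bst2 (-0.013 to 0.099), Camp (-0.15 to 0.29) and Ngp (-0.087 to 0.30). The cause of these differences was not tested. Fits without 1 library gave more than 113 genes in some cases (522 without deficient 1) and fewer in others (1 without control 1). The smaller number of samples alone therefore does not account for the lower counts. Depth limits low genes: 1 count is 0.0703 CPM in control 3.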

Other observations

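All tests in this part were chosen after the results were seen, with a few exceptions. These are the counts over splits of the libraries, the test of genes near Lyz2 and the correlation of granule with dendritic-like scores within genotypes. The Lyz2 test and this correlation nevertheless address patterns that had been seen in the results. Yeats4, part of the Lyz2 pattern, is also among the genes counted near Lyz2.

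A list of chaperones and cochaperones was assembled after Hsph1, Dnaja1 and Hspa8 were seen to rise. Of its 25 measured genes, 6 rose, 0 fell and 19 did not pass; besides those 3, the genes that rose were the Hsp90 and Hsp70 partners Cacybp (log2 fold change 0.34, SE 0.07), Ptges3 (0.34, SE 0.07) and Ppid (0.32, SE 0.05). In all, 23 of the 25 had positive log2 fold changes, with a median of 0.26 (camera p = 4.03e-10; p = 0.0599 with an estimated correlation). Over the 19 genes that did not pass, 17 of them positive, the p was 6.65e-06, or 0.0907 with an estimated correlation. A shift of these genes as a group is therefore not established. Hsp90aa1 and Hsp90ab1 had 0.42 and 0.23 (adjusted p = 0.0758 and 0.0970), and Stip1 0.35 (adjusted p = 0.0560). Hspa1a and Hspa1b, the inducible pair whose reads are nearly identical, had 1.08 (SE 0.70) and 1.10 (SE 0.62), with adjusted p = 0.389 and 0.333. With 1 library left out, Hspa1a ranged from 0.38 to 1.38 and Hspa1b from 0.51 to 1.38. The chaperone score was higher in every deficient library (0.06 to 0.29) than in every control (-0.19 to -0.06; exact permutation p = 0.0286, two-sided, on genes chosen in part because they rose).

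Further genes past the threshold were picked by eye from the 113, and no group among them was tested. Cd40, the costimulatory receptor of antigen-presenting cells, fell (log2 fold change -0.48, SE 0.09, adjusted p = 0.0421), as did Runx2 (-0.32, SE 0.07, adjusted p = 0.0459), Satb1 (-0.41, SE 0.07, adjusted p = 0.0292) and the mitophagy kinase gene Pink1 (-0.34, SE 0.07, adjusted p = 0.0473). Stat3 rose (0.28, SE 0.06, adjusted p = 0.0488), and so did the adenosine receptor gene Adora2b (0.35, SE 0.07, adjusted p = 0.0450). The largest decreases of all were Ndnf (-2.05, SE 0.25, adjusted p = 0.00960) and Tnfsf8 (-1.70, SE 0.26, adjusted p = 0.0292), at means of 1.53 and 1.39 CPM.

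The number of changed genes was set against other splits of the 8 libraries into 4 and 4. Of the 35 splits, 1, the real one, gave 113 genes; the highest of the others gave 7 and 31 gave 0, which argues against a chance split as the source of the whole count. For the lists, 8 of the 35 splits gave at least 14, and the highest of the others gave 20, so chance cannot be excluded for the number of lists past the threshold. The split with 20 lists was the real one with control 1 and deficient 3 exchanged. It keeps most libraries of each genotype together, so it cannot separate genotype from another structure among the libraries.

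At the lysozyme locus, Lyz2 fell and Lyz1 and Yeats4 (log2 fold change 0.27, SE 0.04, adjusted p = 0.0292), the genes on either side, rose. If the same share of reads moved between the paralogs in both groups, Lyz1 would go down with Lyz2, and its log2 fold change of 1.60 goes the other way. That share was not measured, so a share that differs between the groups stays open. The log2 fold change of Lyz2, -1.02 (SE 0.05), is consistent with a lost copy of Lyz2 where Cre was inserted on 1 of 2 chromosomes, which would leave a value of -1. A wider effect of the insertion stays open: of 14 tested genes within 1 Mb, without Lyz1 and Lyz2, 3 had an unadjusted p under 0.05 (21.4%, against 24.0% elsewhere; Fisher's exact test, one-sided p = 0.688), too few to exclude an effect on the nearest genes. Every deficient library carries Cre and no control does, so an effect of Cre or of its insertion cannot be told apart from COMMD10 loss here, at this locus or elsewhere.

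For the chaperone genes that rose and for lower Cirbp, no tested explanation was excluded. Handling stress that induces immediate early genes would raise their score, which differed by -0.22 (SE 0.24) between genotypes, below 0 but within its error. The immediate early list includes Hspa1a and Hspa1b, which are also chaperone genes of the pattern and had positive log2 fold changes. Its score is therefore not independent of the pattern. The chaperone score might follow the first principal component: with group means removed, r was 0.63 (permutation p = 0.148; Spearman rho 0.69, permutation p = 0.135; 8 libraries), and 0.24 without deficient 2 and 3, on which the relation rests. A difference in temperature or collection day is open as well, since the labels give no day: Rbm3, another cold-induced gene, had a log2 fold change of -0.19 (SE 0.05, adjusted p = 0.0736), in the direction of Cirbp. An effect of genotype on protein folding genes stays open and untested.

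For higher primary granule genes with lower dendritic-like genes, a possible explanation was a purer sort of deficient cells. That would lower the markers of every other cell type alike only if all other cells were reduced in the same proportion, which was not measured. The 8 measured neutrophil precursor markers outside the primary granule list and the erythroid markers had score differences of 0.28 (SE 0.13) and -0.52 (SE 0.21). The gap between them, 0.80 (SE 0.30), exceeds 2 standard errors, but its exact permutation p was 0.0571 (two-sided) and monocytes express some precursor markers, so a difference in purity stays open. Neutrophil precursors in the sort might bring late granule genes as well; Camp, Ngp and Ltf had log2 fold changes of 0.15, 0.13 and 0.30, and their score relative to that of Elane, Mpo, Prtn3 and Ctsg differed by -0.58 (SE 0.38), which leaves this open, although the gate removes Ly6G+ and CD117+ cells and asks for CD115. An axis present within genotypes could also account for part of it: with group means removed, the granule and dendritic-like scores correlated at r = -0.58 (permutation p = 0.181; Spearman rho -0.60, permutation p = 0.184; 8 libraries; r = -0.65 without control 1 and deficient 3), which cannot be told from no relation. A shift of monocyte fate with COMMD10 loss remains a hypothesis beside these.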
